A study of Mus musculus with 8 samples.

How the data were processed

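Messenger RNA was sequenced from low-input samples of epidermal Langerhans cells, the resident antigen-presenting cells of the epidermis, taken from wild-type C57BL/6 mice aged 8 weeks. The labels put 4 samples in a control group, whose shaved back skin received Vaseline for 3 days, and 4 samples in an imiquimod (IMQ) group, whose shaved back skin received IMQ for 3 days. Imiquimod is a Toll-like receptor 7 agonist whose cream induces psoriasis-like dermatitis in mice. The labels say that mice were allocated to the groups at random, and do not say how the cells were isolated or whether each sample came from a separate animal or a pool. The p-values therefore measure the spread between these samples, part of which may be technical. Per the labels' protocols, RNA was extracted with TRIzol and made into strand-specific TruSeq libraries.

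Per the submitters' processing notes, FastQC, STAR 2.5, Cuffnorm, DESeq 1.22.1 and the GRCm38 mouse genome build were used, with no role or order given. The read counter, its strand setting and the gene annotation are not given in the sources used here. The authors deposited 1 table of 26572 Ensembl genes with 1 column per sample. Its values were on a log2 scale, and the deposited log2 values were found to be log2(normalized read count + 1). After that transformation was undone, 100% of the values in each of the 8 libraries were whole multiples of a single step per library within a tolerance of 0.02 of a read. The step, the normalized value of 1 read, ran from 0.634 in IMQ replicate 1 to 1.36 in IMQ replicate 4. The table thus holds whole reads per gene divided by 1 factor per library, with no scaling by gene length, and the reads of each library could be recovered.

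The recovered totals ran from 21398547 reads in IMQ replicate 3 to 46130710 in control replicate 4. A gene listed at 0 in a library is compatible with up to 3 reads, which is between 1.9 and 4.08 normalized counts per library. This floor covers counting error only, because PCR copies were not marked by molecular identifiers in the values used. Where a gene was at 0 in all 4 libraries of a group, its fold is given as a lower bound, the geometric mean of the other group divided by 3 reads in the library with the largest step among the libraries at 0. The smallest Pearson correlation of 2 libraries of a group was 0.689, and at least 56.5% of the genes with at least 20 reads in a pair of libraries differed by more than 3 SD of counting noise in every pair, so no library was taken for a copy of another.

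IMQ was compared with control in limma 3.58.1 under R 4.3.3, with eBayes (trend and robust options on) on the deposited log2 values, a pseudocount of 1, and group as the only term. The test was two-sided with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. The 16835 genes with a normalized count of at least 1 in at least 4 of the 8 libraries were tested. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The plan had expected FPKM or raw counts; its branch for normalized values was applied, and its count test was not used because the deposited unit is a log scale. As an added alternative, limma-voom was run on the recovered reads. No other column of per-sample values was present.

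Before the data were examined, 31 gene lists were fixed, covering pathways, Langerhans cell genes and markers of other cells an epidermal sample could hold. Of their 618 genes, 602 were found, by symbol or through the GENCODE M21 name of the gene identifier, and of 2 rows with the same symbol the lower Ensembl number was used. Lists with at least 3 tested members, 28 in all, were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Camera compares the statistics of a list's genes with those of all other tested genes, so its direction can differ from the sign of the list's median. Counts over a list were taken after adjustment over all genes tested and again adjusted over the list alone.

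Genes named in the text followed a rule fixed with the lists. It took the 10 largest rises and the 10 largest falls among genes called, with groups that did not overlap and a mean normalized count of at least 5, leaving out predicted genes. It added up to 4 members of each list with the smallest p and any member needed to say what the list did. It always gave a fixed set of marker genes, among them Cd207, Epcam, Il1b, Tlr7, Krt14, Cd3e and S100a8. Genes under the filter were given as values with no test. The values of a few genes that the rule names are not reported here. Coordinates and gene biotypes came from GENCODE M21 on GRCm38, in which 26519 of the 26572 identifiers were found.

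The fitting steps were tested on simulated data, drawn from negative binomial counts with the real means, library factors and within-group spread and 19376 genes tested. In that simulated IMQ against control comparison, 18 of 100 genes changed 4-fold and 86 of 100 genes changed 32-fold were called in the right direction, with 2 unchanged genes called. Both lists of 20 genes changed 4-fold were called by camera, as was 1 of 20 lists of unchanged genes. The simulated genes were drawn independently, so these list results do not give the rate of false calls for real lists, whose genes vary together. The alternatives covered the pseudocount, the filter, scaling between libraries, moderation, library weights, a replicate block, each library left out and a stricter threshold. Alternatives chosen after the data were seen were voom, covariates for keratinocyte RNA and genes detected, fits without 3 libraries, and a filter at a mean of 100. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.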

Results

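The data were 8 RNA-seq libraries of mouse epidermal Langerhans cells, 4 from Vaseline-treated control skin and 4 from skin treated with imiquimod for 3 days. The recovered read totals were 32958777, 40315430, 43729972 and 46130710 in control replicates 1 to 4 and 42641462, 34019219, 21398547 and 29340980 in IMQ replicates 1 to 4. Genes with at least 1 read numbered 14797, 17977, 20705 and 20279 in the controls and 12813, 11894, 15235 and 20244 in the IMQ libraries. The group means, 18440 ± 2708 and 15046 ± 3741 genes (SD, n = 4), did not differ beyond the spread (exact permutation test, two-sided, p = 0.2).

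Markers of keratinocytes, the main cell of the epidermis, varied widely within both groups. Their mean over the list was 10.1 and 9.46 on the log2 scale in control replicates 3 and 4 and 8.60 in IMQ replicate 4, against 3.50 and 6.09 in control replicates 1 and 2 and between 2.51 and 3.32 in IMQ replicates 1 to 3. Krt14, a basal keratin, was at 14.72 and 15.56 in control replicates 3 and 4 and at 15.62 in IMQ replicate 4, and between 8.45 and 11.45 in the other 5 libraries. Neither Krt14 (12.51 ± 3.08 in control, 11.48 ± 3.03 in IMQ, SD, n = 4, limma adjusted p = 0.796) nor Krt5 (10.26 ± 2.65 and 9.08 ± 2.37, adjusted p = 0.711) differed between the groups beyond the spread. The pan-leukocyte gene Ptprc was at 12.14 ± 0.52 and 12.24 ± 0.71 (adjusted p = 0.92).

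**Figure D1:**
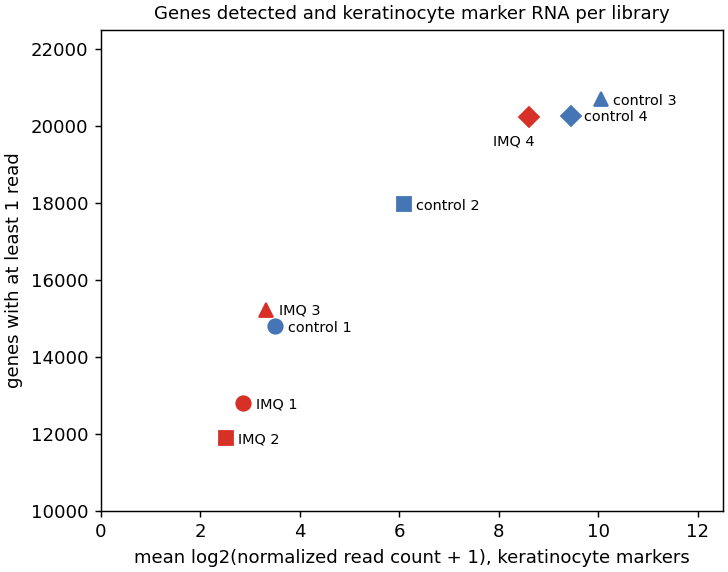
Number of genes with at least 1 read (vertical axis) against the mean log2(normalized read count + 1) of the keratinocyte markers (horizontal axis), 1 point per library, control blue and IMQ red. IMQ replicate 4, with 20244 genes and a keratinocyte mean of 8.60, lies with control replicates 3 and 4, and control replicate 1, with 14797 genes and 3.50, lies with IMQ replicates 1 to 3.

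The comparison of the groups asks how the Langerhans cell transcriptome differs in imiquimod-induced, psoriasis-like dermatitis. Among the genes that rose in IMQ were the alarmins S100a8 and S100a9, the acute-phase gene Saa3, the chitinase-like Chil3, the cytokines Osm and Il1b, and complement C1q. The Langerhans cell lectin Cd207, the leukotriene synthase Ltc4s, the costimulatory gene Cd83 and Tnf fell. Of 16835 genes tested, 96 were higher and 92 lower in IMQ (limma, adjusted p under 0.05), and the 4 IMQ values of each called gene lay entirely above or below the 4 control values. Over all tested genes 11.1% did not overlap between the groups. For a single gene with its 8 values in random order the chance of this is 2.86%. Genes vary together, so the share in 1 split of the libraries can lie far from 2.86%. The comparison of these shares is thus no test of treatment. The calls had an absolute log2 fold change of at least 1.34, with a median of 3.78.

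These counts rested on single libraries. Without control replicate 2, 3 or 4 there were 20, 29 or 24 genes higher and 10, 10 or 11 lower. Without IMQ replicate 1, 2 or 3 there were 38, 41 or 39 higher and 40, 31 or 30 lower, without control replicate 1 there were 83 and 78, and without IMQ replicate 4 there were 271 and 661. The median log2 fold change of all tested genes was −0.49, and −0.07 among the 5841 genes with a mean log2 value above 8. With the library medians set equal, which moved the median to −0.03, 86 genes were higher and 25 lower, a share of 77.5% higher in place of 51.1%. The median changed sign under that scaling or quantile normalization for 6 lists, none of them called: Langerhans cell identity, endosomal Toll-like receptor signalling, cell cycle, lysosome and autophagy, B cell and erythroid genes. Without the 3 keratinocyte-rich libraries (control replicates 3 and 4, IMQ replicate 4) 5 genes were higher and none lower, with 1821 genes at an unadjusted p under 0.05 in limma. Without the 3 libraries with under 15000 genes detected (control replicate 1, IMQ replicates 1 and 2) the counts were 8 and 5. Of the 65 genes called and followed across alternatives, 13 stayed called whichever single library was left out: C1qb, Ifitm1, Lcn2, Lilr4b, Mmp9, Ms4a6d, Osm, Pilra, Rbfox1, S100a8, S100a9, Saa3 and Sprr2d. Of these 13, voom on the recovered reads ended the calls of Ifitm1, Lilr4b, Osm, S100a8, S100a9 and Saa3, the replicate block those of Lcn2 and Pilra, eBayes without trend and robust that of Mmp9 and a pseudocount of 0.01 those of Ifitm1 and Pilra, and each of the 13 lost its call without 1 or both of the sets of 3 libraries. Each of the others lost its call without at least 1 library, the highest adjusted p lying between 0.0567 for Jund and 0.162 for H2-M6-ps. With keratinocyte markers as a covariate 25 of the 65 stayed called, and with genes detected as a covariate 25. Among the genes higher in IMQ, those that lost their call with either covariate included C1qa, C1qc, Chil3, Fpr1, Sirpb1c, Mmp8, Il1rn, Ldha, Fdps, Ifi30, Cenpa and Id1. Among the genes lower they included Cd207, Tnf, Cd83, Ltc4s, Jund, Klf6, Nfkbie, Gabarapl1 and Atf3. No called gene changed direction under any alternative that was run.

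At a pseudocount of 1 the largest rise was that of Ifitm1, an interferon-inducible membrane protein, by 11.74 on the log2 scale (SE 1.45, limma adjusted p = 0.011, 0.073 at a pseudocount of 0.01, where its rise was not the largest), from 2.88 ± 3.33 to 14.62 ± 1.12 (SD, n = 4). Saa3 (chromosome 7, 46711998 to 46715700, GRCm38) rose by 11.27 (SE 1.31, adjusted p = 0.00849). Chil3, a product of alternatively activated macrophages, rose by 10.59 and was at 8.75 in IMQ replicate 4 against at least 13.17 in the other IMQ libraries. Lcn2, the iron-sequestering lipocalin, had no read in any control and was at least 333-fold higher in IMQ. On the same basis the formyl peptide receptor Fpr1 was at least 187-fold higher, the activating myeloid receptor Tarm1 at least 263-fold and the cornified-envelope gene Sprr2d at least 224-fold. Without IMQ replicate 4 the bounds were 614-fold for Lcn2, 470-fold for Fpr1 and 559-fold for Tarm1. The lowest bounds with 1 library left out were 217-fold for Lcn2 (without IMQ replicate 3), 167-fold for Tarm1 (IMQ replicate 2) and 129-fold for Fpr1 (IMQ replicate 1). That of Sprr2d ran from 179-fold without IMQ replicate 4 to 293-fold without control replicate 4. Sirpb1c, a signal-regulatory protein, rose by 10.17, BC100530, a stefin A family member, by 10.13, and the neutrophil collagenase Mmp8 by 9.37. Sirpb1c, BC100530 and Sprr2d belong to families of near-identical copies among which reads could be split, so their values are uncertain.

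Among the largest falls was that of Rbfox1, a splicing regulator (chromosome 16, 5885355 to 7411526), which had between 376 and 798 reads in each control library and none in any IMQ library, at least 148-fold lower (limma adjusted p = 0.00717). The kinase gene Ripk4 fell by 8.84, the centrosomal gene Ninl by 7.89, the tetraspanin Tspan32 by 7.56, the epidermal lipoxygenase Aloxe3 by 7.44, the betaine transporter Slc6a12 by 7.33 and Triqk by 7.14. The keratin Krt77 and the circadian repressor Per2 had no read in any IMQ library and were at least 58-fold and at least 29.6-fold lower. The bound of Krt77 was 124-fold without control replicate 1, 29.2-fold without control replicate 3 and 37.1-fold without control replicate 4. That of Per2 was 52.8-fold without control replicate 2, 20.2-fold without control replicate 3 and 22.7-fold without control replicate 4. H2-M6-ps, an unprocessed pseudogene of the major histocompatibility complex, fell by 7.61 and may share reads with its paralogs. For Ripk4, H2-M6-ps, Aloxe3, Slc6a12 and Triqk, IMQ replicate 4 held reads while IMQ replicates 1 to 3 were at 0. Of the falls named in this paragraph, only that of Rbfox1 stayed called with keratinocyte markers or genes detected as a covariate.

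**Figure D2:**
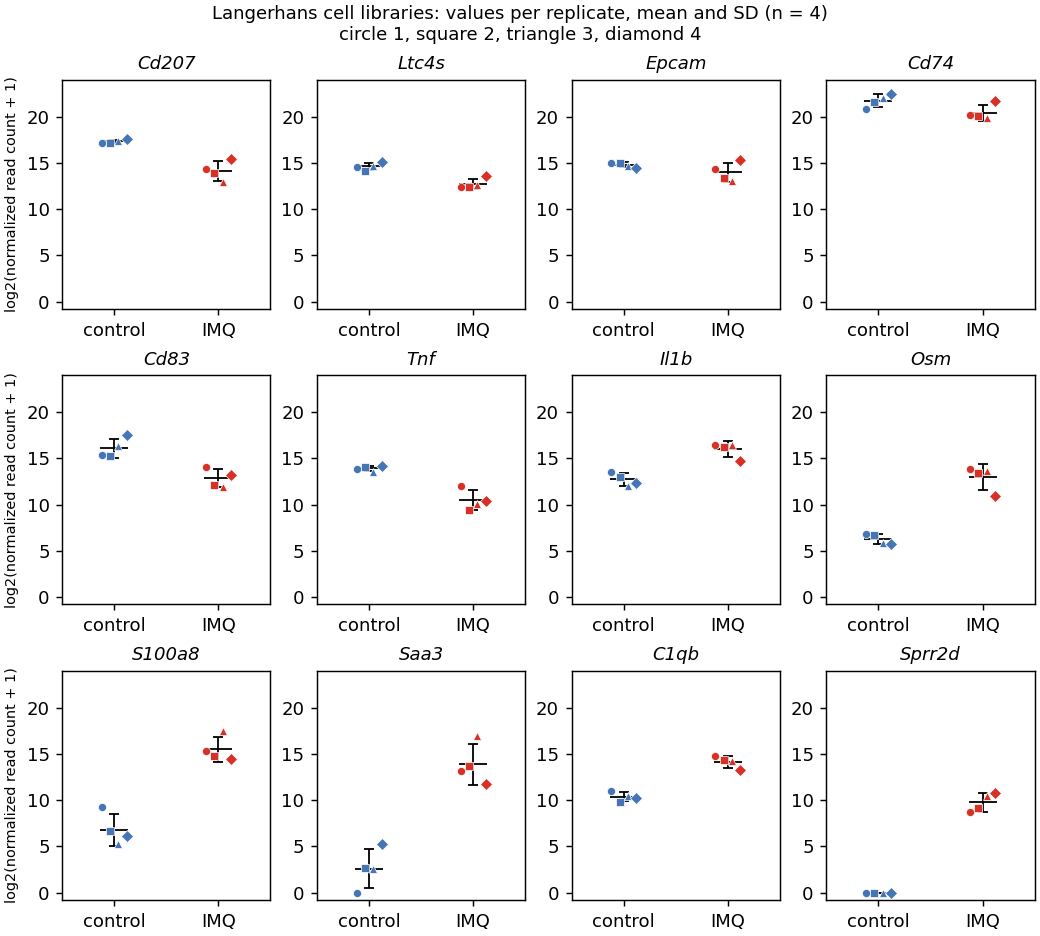
Values of 12 genes on the log2(normalized read count + 1) scale, 1 point per library with the mean and SD of each group (n = 4), control blue and IMQ red, the marker shape giving the replicate number. Cd207 falls from a mean of 17.33 to 14.16 and S100a8 rises from 6.81 to 15.50, while Epcam, at 14.81 and 14.02, overlaps between the groups.

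Among the 20 genes of Langerhans cell identity, 2 fell and none rose over all genes tested, and the same count held adjusted over the list alone. Cd207 (langerin, chromosome 6, 83671215 to 83677857), the lectin of Birbeck granules, fell by 3.18 (SE 0.456, limma adjusted p = 0.017), from 17.33 ± 0.21 to 14.16 ± 1.05, 9.05-fold. Its adjusted p lay between 0.00608 and 0.0659 with 1 library left out and passed 0.05 without control replicate 2 (0.0567), 3 (0.0659) or 4 (0.0648) and without IMQ replicate 2 (0.0526). The call was also lost with keratinocyte markers as a covariate (log2 fold change −2.71, adjusted p = 0.0617), with genes detected as a covariate (−2.76, 0.0692), with eBayes without trend and robust (0.0769), without the 3 keratinocyte-rich libraries (0.138) and without the 3 libraries with under 15000 genes detected (0.157). Ltc4s, the leukotriene C4 synthase, fell by 1.89 (adjusted p = 0.0317), and stayed called with 1 library left out only without IMQ replicate 4 (0.00875, highest 0.118). Epcam, the adhesion molecule of Langerhans cells, was at 14.81 ± 0.28 and 14.02 ± 1.02 (adjusted p = 0.427), the E-cadherin gene Cdh1 was 0.92 higher (adjusted p = 0.176) and Ahr had a log2 fold change of −1.02 (adjusted p = 0.218), none of them past the threshold. The list as a set was not called (camera adjusted p = 0.939). Its median was −0.34 (0.13 with the library medians set equal) and camera's direction was upward.

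In the MHC class II list, Cd74, the invariant chain, was at 21.75 ± 0.68 in control and 20.45 ± 0.87 in IMQ (adjusted p = 0.237) and H2-Ab1 at 21.71 ± 0.94 and 20.34 ± 1.11 (adjusted p = 0.329). Of 15 members 1 rose over all genes tested, the lysosomal thiol reductase Ifi30 (annotated as a processed transcript), by 1.42 (SE 0.261, adjusted p = 0.038). Adjusted over the list alone, 3 were higher and 5 lower, and the set was not called (camera adjusted p = 0.765). The MHC class I list was called upward by camera (adjusted p = 0.0222) with a median log2 fold change of 0.07 and no member called over all genes, and 4 higher adjusted over the list alone. Its members with the smallest p were the immunoproteasome genes Psme2 (1.69 higher, adjusted p = 0.0572), Psmb10 (1.62, 0.0916), Psme1 (0.81, 0.119) and Psmb9 (1.27, 0.149). The list's adjusted p was 0.334 with an estimated correlation, and it was 0.143 without IMQ replicate 4.

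Maturation genes did not move as a block. Cd83 fell by 3.24 (SE 0.599, limma adjusted p = 0.039), from 16.10 ± 1.06 to 12.86 ± 0.98, and stayed called with 1 library left out only without IMQ replicate 1 (0.0433) or 4 (0.0331), with a highest value of 0.126. It was the only one of 24 members called over all genes tested, against 5 higher and 1 lower adjusted over the list alone. Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 8.41 ± 1.14 and 10.61 ± 1.73 (adjusted p = 0.285), and the costimulatory gene Cd86 at 14.26 ± 0.38 and 13.47 ± 0.67 (adjusted p = 0.333). Pdcd1lg2, encoding PD-L2, was 5.59 higher (adjusted p = 0.0881), Ccl5 3.18 higher (0.104) and Marcks 1.83 higher (0.114). The list was called upward by camera (median 1.52, adjusted p = 0.00153), with an adjusted p = 0.292 with an estimated correlation.

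Of 23 tested cytokine and chemokine genes, 3 rose and 1 fell over all genes tested, and 6 rose and 1 fell adjusted over the list alone. Osm, oncostatin M (chromosome 11, 4236420 to 4241026), rose by 6.71 (SE 0.651, limma adjusted p = 0.00588), from 6.28 ± 0.54 in control to between 10.97 and 13.91 in the IMQ libraries, 105-fold. Il1b (chromosome 2, 129364570 to 129371139) rose by 3.25 (SE 0.468, adjusted p = 0.017), 9.54-fold, with an adjusted p between 0.00678 and 0.0648 with 1 library left out, under 0.05 only without control replicate 1 or IMQ replicate 4. The interleukin 1 receptor antagonist Il1rn rose by 3.80 (adjusted p = 0.0302), and with 1 library left out stayed called only without control replicate 1 (0.0454) or IMQ replicate 4 (0.00868). Tnf fell by 3.43 (SE 0.502, adjusted p = 0.018), from 13.93 ± 0.31 to 10.50 ± 1.12, 10.8-fold, and lost its call without control replicate 2 (0.071), 3 (0.0604) or 4 (0.0727) or IMQ replicate 3 (0.058). The call of Tnf was also lost with keratinocyte markers (0.0696) or genes detected (0.0727) as a covariate, with the replicate block (0.0601), with eBayes without trend and robust (0.0722) and without the 3 keratinocyte-rich libraries (0.198). Il23a, a subunit of interleukin 23, was at 6.98 ± 2.06 and 6.34 ± 1.94 (adjusted p = 0.844). The list was called upward by camera (median 1.14, adjusted p = 3.74e-06), with an adjusted p = 0.126 with an estimated correlation. Whichever single library was left out it stayed called, with an adjusted p of at most 0.000133.

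Tlr7, the receptor of imiquimod, was close to the floor, with values of 0, 2.40, 0 and 2.28 in the controls and 0, 0, 5.79 and 0 in IMQ, and was not tested. Of 22 tested genes of endosomal Toll-like receptor signalling 1 was called, the NF-kB inhibitor Nfkbie, which fell by 1.60 (adjusted p = 0.0342), against 2 higher and 3 lower adjusted over the list alone. Other NF-kB feedback genes did not pass the threshold, with log2 fold changes of −2.12 for Tnfaip3 (adjusted p = 0.0526) and −2.44 for Nfkbia (0.121), while the trafficking chaperone Unc93b1 was 3.10 higher (0.0943). The set was not called (camera adjusted p = 0.681), with a median of −0.27 and an upward direction relative to all genes. No interferon-stimulated gene of 28 tested was called by limma over all genes, and 4 were higher adjusted over the list alone. Those with the smallest p were Oasl2 (5.12 higher, adjusted p = 0.0842), Gbp3 (5.10, 0.108), Oas3 (2.20, 0.12) and Oas1a (2.13, 0.0699). Irf7 was at 7.26 ± 1.04 and 7.16 ± 3.09 (adjusted p = 0.98). Camera called this list upward (median 0.68, adjusted p = 0.00252), with an adjusted p = 0.328 with an estimated correlation. Its mean was 5.93 and 5.87 in IMQ replicates 1 and 2, below every control, and 8.52 and 8.05 in IMQ replicates 3 and 4.

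The list with the largest shift was the epidermal response to IL-17 and IL-36. Of 16 tested members 7 rose and none fell over all genes tested (12 higher adjusted over the list alone), namely S100a8, S100a9, Lcn2, Sprr2d, Sprr1b, Sprr2h and Stfa3. S100a8 (chromosome 3, 90668978 to 90670035) rose by 8.69 (SE 0.897, limma adjusted p = 0.00638), from 6.81 ± 1.72 to 15.50 ± 1.36, and S100a9 by 8.70 (SE 1.05, adjusted p = 0.0105). The list median was 7.28, also with its 2 genes at 0 in all controls set to their bound (camera adjusted p = 1.13e-17), and it was the only list called with an estimated correlation, at an adjusted p = 0.0429. The list mean was between 8.63 and 10.2 in IMQ replicates 1 to 3 and 11.7 in IMQ replicate 4, the IMQ library with the highest keratinocyte markers, where Krt6a reached 13.41 and Krt16 13.95. The interleukin 17 and 22 genes themselves were at or near 0: Il17f had 61 reads, Il17a 15, Il22 7 and Il23r 5 in IMQ replicate 4, and the only other reads were 3 of Il17a in control replicate 4.

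Some neutrophil and monocyte markers also rose. Among 14 tested neutrophil genes 6 rose and 1 fell over all genes tested (9 and 2 adjusted over the list alone). Those that rose were S100a8, S100a9, Lcn2, Mmp8, Mcemp1 and Trem1, the first 3 of which the epidermal list also holds. Mmp9, the gelatinase, fell by 3.69 (SE 0.462, adjusted p = 0.0111). The granule genes Ngp and Camp and the surface marker Ly6g had 514, 217 and 146 reads in IMQ replicate 3 and at most 3 in any other library. Camera called the list upward (median 5.01, adjusted p = 1.63e-09), with an adjusted p = 0.0887 with an estimated correlation. Among 21 monocyte and macrophage genes 5 rose and none fell (15 higher adjusted over the list alone): Chil3, Ms4a7 and the complement genes C1qa, C1qb and C1qc. C1qb rose by 3.76 (SE 0.376, adjusted p = 0.00638), from 10.39 ± 0.49 to 14.15 ± 0.65, C1qa by 2.10 (SE 0.282, adjusted p = 0.0125, 0.0604 without control replicate 3) and C1qc by 3.31 (adjusted p = 0.0317, called with 1 library left out only without control replicate 1, 0.0251, or IMQ replicate 4, 0.0128). Lyz2, lysozyme, was between 15.98 and 16.81 in IMQ replicates 1 to 3 and at 13.44 in IMQ replicate 4, against 12.64 to 13.58 in the controls (adjusted p = 0.0915). Camera called the list upward (median 3.93, adjusted p = 7.16e-17), with an adjusted p = 0.0945 with an estimated correlation. In both lists IMQ replicate 4 had the lowest mean of the IMQ libraries, 8.27 and 8.65, and every control lay lower still.

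**Figure D3:**
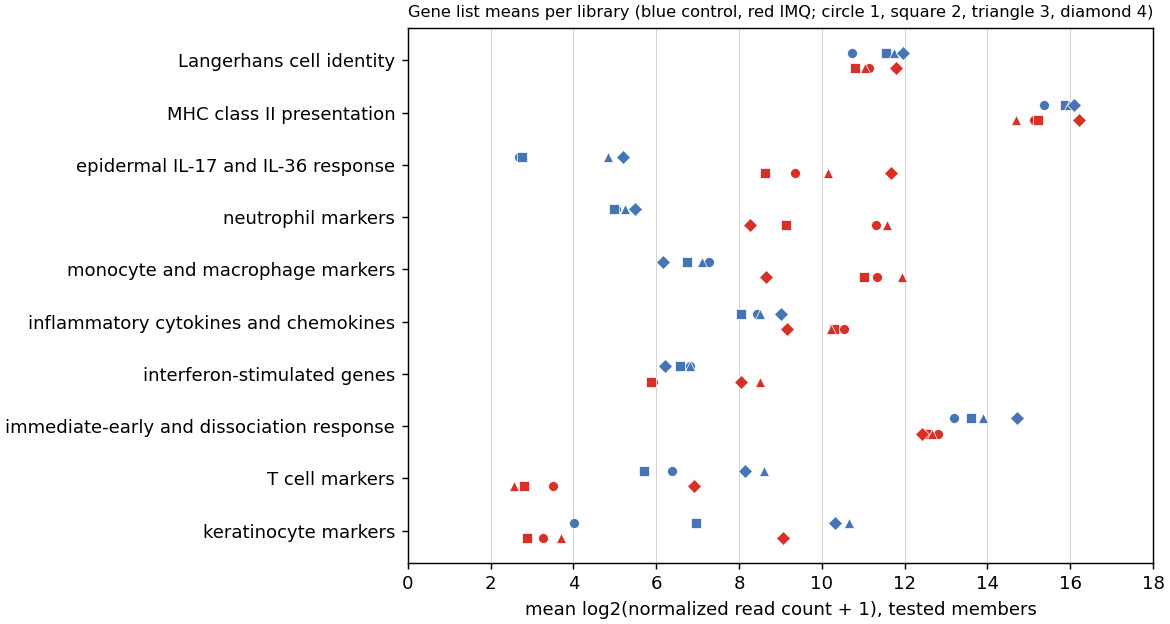
Mean log2(normalized read count + 1) over the tested members of 10 gene lists (horizontal axis), 1 point per library, control blue and IMQ red, the marker shape giving the replicate number. IMQ replicate 4 (diamond) has the highest mean of the IMQ libraries for T cell markers, 6.91, and keratinocyte markers, 9.07, and the lowest for monocyte and macrophage markers, 8.65.

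T cell markers, which in mouse epidermis include those of dendritic epidermal T cells, were lower as a set (camera, median −4.57, adjusted p = 4.49e-05; adjusted p = 0.384 with an estimated correlation), with none of 20 tested members called by limma over all genes or adjusted over the list alone. Cd3e was between 5.31 and 7.98 in the controls, at 0 in IMQ replicates 1 to 3 and at 6.90 in IMQ replicate 4 (SE 1.75, adjusted p = 0.229). The log2 fold changes were −5.99 for Cd3g (adjusted p = 0.112), −6.12 for Cd2 (0.15) and −4.59 for Zap70 (0.173). The keratinocyte markers were lower as a set (median −3.14, camera adjusted p = 0.0102; adjusted p = 0.646 with an estimated correlation). The call was lost without control replicate 3, control replicate 4 or IMQ replicate 3, with a highest adjusted p = 0.0867. Of 21 tested members 1 fell over all genes tested, Krt77, and 2 adjusted over the list alone. Without passing the threshold, the log2 fold changes were −9.85 for Krt15 (adjusted p = 0.082), −6.16 for Dmkn (0.299) and −5.34 for Lamb3 (0.216).

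Immediate-early genes, which respond to stimuli and to tissue dissociation, were lower in IMQ as a set (median −1.37, camera adjusted p = 0.000116; adjusted p = 0.368 with an estimated correlation). Over all genes tested 2 of 25 fell and none rose, against 13 lower and 1 higher adjusted over the list alone. Jund fell by 2.55 (SE 0.344, limma adjusted p = 0.0125, 0.0567 without control replicate 2) and Klf6 by 1.64 (SE 0.288, adjusted p = 0.0338, at most 0.126 with 1 library left out). Not called were Fos, with a log2 fold change of −2.45 (adjusted p = 0.0633), and Nr4a1, with −1.81 (0.0706). The unfolded protein response list was not called (median −0.89, camera adjusted p = 0.301). Its transcription factor Atf3 fell by 1.91 (adjusted p = 0.0434), 1 of 19 over all genes and 3 adjusted over the list alone, while the log2 fold changes of Dnajb9, Hspa5 and Hsp90b1 were −1.74 (0.0526), −1.46 (0.135) and 0.75 (0.198).

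Metabolic lists moved upward by camera. In glycolysis and hypoxia 2 of 23 genes rose over all genes tested, and 7 rose and 1 fell adjusted over the list alone (median 0.82, camera adjusted p = 3.23e-07; adjusted p = 0.0887 with an estimated correlation). Pgk1 rose by 1.64 (SE 0.232, limma adjusted p = 0.0143) and Ldha by 1.76 (SE 0.283, adjusted p = 0.0254), Slc16a3 was 2.37 higher (0.0526) and Pgam1 0.92 higher (0.105). In cholesterol and lipid metabolism the fatty acid binding protein Fabp5 rose by 4.46 (adjusted p = 0.0333) and the sterol enzyme Fdps by 1.75 (0.037), 2 of 27 over all genes and 4 adjusted over the list alone. Plin2 was 1.18 higher (0.104) and Fdft1 1.75 higher (0.106). That list had a median of 0.48 (camera adjusted p = 0.00362; adjusted p = 0.249 with an estimated correlation). All 13 mitochondrially encoded genes had a positive fold change with none called by limma over all genes or adjusted over the list alone (median 0.90, camera adjusted p = 0.000116; adjusted p = 0.384 with an estimated correlation). The call of this list, the mitochondrially encoded genes, was also lost with keratinocyte markers as a covariate (0.219), with genes detected as a covariate (0.365) and without the 3 libraries with under 15000 genes detected (0.447). Its leading members were mt-Co2 (1.39 higher, limma adjusted p = 0.218) and mt-Nd6 (1.76, 0.288). The share of reads from mitochondrial genes was 9.38, 10.02 and 7.12% in IMQ replicates 1 to 3, 2.08% in IMQ replicate 4, and 2.38, 5.31, 1.72 and 1.82% in the controls. The 32 ribosomal protein genes had a median of 0.35 (camera adjusted p = 0.000116; adjusted p = 0.368 with an estimated correlation), with none called over all genes and 1 higher adjusted over the list alone. The 31 nuclear oxidative phosphorylation genes had a median of 0.24 (camera adjusted p = 0.0102; adjusted p = 0.384 with an estimated correlation) with none called either way, and the call was lost without control replicate 4 or IMQ replicate 4, with a highest adjusted p = 0.0675. Ribosomal and Pgk1 reads may be shared with their processed pseudogenes.

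Of 23 cell death regulators none was called over all genes and 2 were higher adjusted over the list alone, Bcl2a1d (1.88 higher, limma adjusted p = 0.0637) and Bcl2a1a (1.87, 0.0907), survival genes of a family of near-identical copies, so that these values are uncertain. Camera called the list upward (median 0.64, adjusted p = 0.000381; adjusted p = 0.0783 with an estimated correlation). In the inflammasome list, not called (median 0.32, mean −0.05, camera adjusted p = 0.207), Txnip fell by 2.16 (adjusted p = 0.0342) as 1 of 14, with 1 higher and 2 lower adjusted over the list alone, while the adaptor Pycard was 1.34 higher (0.0576) and Gsdmd 1.45 higher (0.222), and Nlrc4 was at 7.18 ± 0.77 in control and 2.27 ± 2.64 in IMQ (0.15). In the lysosome and autophagy list (median −0.31, upward by camera, adjusted p = 0.888) 1 of 25 genes rose and 1 fell over all genes tested, against 1 higher and 2 lower adjusted over the list alone. Gabarapl1 fell by 2.58 (adjusted p = 0.0222). In the cell cycle list (median −0.58, upward by camera, adjusted p = 0.156) the centromeric histone Cenpa rose by 2.10 (adjusted p = 0.0309), 1 of 30 over all genes and adjusted over the list alone. That list was called upward under 5 alternatives: without IMQ replicate 2 (adjusted p = 0.00178), with arrayWeights (0.0197), with keratinocyte markers (0.0217) or genes detected (0.00333) as a covariate and without the 3 libraries with under 15000 genes detected (3.07e-08). The mean of the cell cycle list was 5.75 and 4.24 in IMQ replicates 1 and 2, below every control. In IMQ replicates 3 and 4 it was 8.73 and 9.67, above every control. In TGF-beta and BMP signalling (median −0.47, upward by camera, adjusted p = 0.888) Id1 rose by 1.65 (adjusted p = 0.0474), 1 of 15 over all genes and adjusted over the list alone.

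Camera did not call other dendritic cell genes (15 tested, median 0.18, mean −0.78, adjusted p = 0.691, none called over all genes, 1 higher and 1 lower adjusted over the list alone), among which Flt3 was 1.19 higher (limma adjusted p = 0.0841) and Cadm1 had a log2 fold change of −2.36 (0.101). B cell (3 tested, median −0.05, adjusted p = 0.966) and erythroid genes (4 tested, median −1.09, adjusted p = 0.187) were not called either. The endothelial list had 3 tested members and was called upward (median 1.27, adjusted p = 0.043; adjusted p = 0.292 with an estimated correlation), led by Pecam1 (5.68 higher, limma adjusted p = 0.0842), which leukocytes also express. The call was lost without control replicate 1 or IMQ replicate 2, 3 or 4, with a highest adjusted p = 0.236. Fibroblast, melanocyte, and mast cell and basophil lists had 2, 1 and 2 tested members and no set test. None of these genes was called by limma over all genes, and 1 fibroblast gene, Sparc, was lower adjusted over the list alone (log2 fold change −5.14, adjusted p = 0.224 over all genes). The basophil protease Mcpt8 had 1237 reads in IMQ replicate 2 and at most 4 in any other library.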

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

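The tests of the neutrophil and monocyte genes, of Cd207 and of keratinocyte carry-over for the T cell markers were chosen after the results were seen. In 130 groups of 4 libraries, gene values and list means were searched for 1 library far from the other 3, and 18 were found. A rate of 1 in 20 would give 6.5 if the values were independent and normally distributed. These values are not, since genes and lists vary together and some genes had no read in the other 3 libraries. The comparison of 18 with 6.5 is thus no test, and the 18 are given as a description. The values are on the log2(normalized read count + 1) scale.

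Control replicate 1 lay below the other controls in 6 of these. Its list means were 11.55 for MHC class I (12.13 to 12.16 in the others), 6.51 for the inflammasome (7.88 to 8.03), 7.72 for cholesterol and lipid metabolism (8.70 to 8.74), 6.67 for other dendritic cells (7.90 to 7.93) and 0.58 for endothelial markers (4.63 to 5.10), and its Il23a value was 3.92 (7.73 to 8.32). IMQ replicate 4 lay apart from the other IMQ libraries in 10. Its keratinocyte mean over the tested members of the list was 9.07 (2.87 to 3.69). Cd3e was at 6.90, Ripk4 at 5.34, H2-M6-ps at 5.64, Aloxe3 at 4.59, Slc6a12 at 3.40 and Triqk at 3.73 where the other 3 were at 0. It lay below the others for Chil3 at 8.75 (13.17 to 13.49), Fpr1 at 5.52 (10.5 to 11.1) and Il1b at 14.71 (16.22 to 16.5). The remaining 2 were Sirpb1c at 4.37 in control replicate 3 and Tlr7 at 5.79 in IMQ replicate 3, each with the other 3 libraries at 0.

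Of the 35 ways to split the 8 libraries 4 against 4, 2 called at least as many genes as the real split with 188, so chance was not excluded for the count of genes. The other one called 1310 genes, 1262 of them lower in control replicate 1 with IMQ replicates 1 to 3 and 48 higher, and shared 1 gene with the 188. In that split, which keeps 3 libraries of each treatment together, 8 of 35 neutrophil and monocyte markers were higher, and 10 of 21 keratinocyte markers and 3 of 20 T cell markers lower, in control replicate 1 with IMQ replicates 1 to 3; the sets were not tested there. Those 4 libraries detected between 11894 and 15235 genes and the other 4 between 17977 and 20705, which points to a structure of the samples that follows genes detected. Because the split keeps 3 libraries of each treatment together, this structure cannot be fully told apart from treatment. The remaining 33 splits called none. For the 17 lists called, 1 of the 35 splits, the real one, called as many, the smallest share that 35 splits allow. The margin was small, since the highest other called 15 and 7 of the 34 others called at least 10. The real split thus called the most lists, but a part due to the structure of the samples was not excluded. Of the 34 other splits, 31 called at least 1 list, with a median of 5, so that a call of a single list was common in splits other than that of treatment.

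Neutrophil and monocyte genes were higher in IMQ, with a median log2 fold change of 4.33 over 35 genes. With the keratinocyte markers as a covariate the median was 3.30 (SE 0.545) and with genes detected it was 2.96 (SE 0.545). The SE is taken over the 35 genes, which vary together, and does not measure the spread between libraries. The medians thus stayed positive with either covariate. Control replicate 1 was near IMQ replicates 1 to 3 in keratinocyte markers and genes detected. Its neutrophil and monocyte list means were 5.03 and 7.28, against 9.12 to 11.58 and 11.01 to 11.94 in those IMQ libraries. IMQ replicate 4, near control replicates 3 and 4 in both measures, had 8.27 and 8.65. Those controls had 5.24 and 5.49 for the neutrophil list and 7.11 and 6.16 for the monocyte list. These values argue against keratinocyte RNA or fewer detected genes as the whole cause, though each comparison rests on 1 library of a group. Other myeloid cells among the Langerhans cells cannot be told apart from induction of these genes by imiquimod within the Langerhans cells, since the 11 neutrophil genes outside the epidermal list, with a median of 4.62 and 8 of 11 positive (permutation p = 0.0286), would be higher under either. That every gene be higher was asked after the values were seen; by the median and the permutation p alone, the rule before, other myeloid cells were favoured. In the controls 2 of 14 tested neutrophil genes and 7 of 21 monocyte genes had a mean of at least 8. The labels do not give how the cells were isolated.

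Cd207 was lower in IMQ. With each library's median log2 ratio set to 0 its log2 fold change was −2.72 (SE 0.449, adjusted p = 0.0264), which argues against scaling of the libraries as the cause; its adjusted p over all alternatives ran from 0.00344 to 0.157. The other 19 genes of the list had a median of −0.18 (SD 1.86), above the −3.18 of Cd207 by more than their SD but less than 2 SD, which argues against a lower share of Langerhans cells as the whole cause, at a margin of 1 SD that replaced 2 SD, under which it was undecided, after the values were seen. With the keratinocyte markers as a covariate the log2 fold change of Cd207 was −2.71 and no longer called (adjusted p = 0.0617), so a part due to the make-up of the samples stays open, as does a change within the cells.

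T cell markers were lower in IMQ, with a median of −4.57. None of 10000 random lists matched on mean level had a median as low (percentile 0, random lists −0.85, −1.95 to 0.12). Their genes were drawn independently, while the genes of this list vary together (estimated correlation 0.559). The spread of the random lists is thus too narrow to decide on fewer detected genes as the cause. With the keratinocyte markers as a covariate the median was −2.53 (SE 0.478 over the genes of the list, not between libraries). Less epidermal carry-over in the IMQ libraries thus cannot be told apart from a loss of T cells under imiquimod. IMQ replicate 4, at a list mean of 6.91, lay within the range of the controls, 5.70 to 8.61. It lay below control replicates 3 and 4 (8.61 and 8.15), the controls nearest to it in keratinocyte markers. Control replicate 1, low in keratinocyte markers like IMQ replicates 1 to 3, was at 6.38, against 2.57 to 3.5 in them. Each of these comparisons rests on 1 library of a group.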

How the results depend on the processing

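The alternatives chosen after the data were seen were voom on the recovered reads with and without quality weights, the covariates, the fits without 3 libraries and the filter at a mean of 100. DESeq2 and a count filter, planned for raw counts, were not run because the table holds log2 values, and moderation without trend has no bearing on the list test. Against 96 genes higher and 92 lower, quantile normalization gave 202 and 158, the median log2 ratio set to 0 gave 86 and 25, eBayes without trend and robust 43 and 42, library weights (arrayWeights) 171 and 237, voom 42 and 65, voom with quality weights 247 and 146, the keratinocyte covariate 40 and 23, and genes detected as a covariate 41 and 19. Without the 3 keratinocyte-rich libraries 5 and 0 were called, without the 3 libraries with under 15000 genes detected 8 and 5, and at an adjusted p under 0.01 12 and 5. With 1 library left out the counts ran from 20 to 271 higher and from 10 to 661 lower, the extremes falling without control replicate 2 and without IMQ replicate 4. Pseudocounts of 0.1 and 0.01 gave 86 and 81 higher and 97 and 118 lower, and filters at none, a mean of 5 and a mean of 100 gave 88, 107 and 141 higher and 73, 87 and 101 lower. No gene called among the 188 changed direction in any of these. Smaller fits hold fewer libraries; for the other changes the cause was not tested.

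The replicate numbers did not pair the samples: the correlations of deviations from the group mean for numbers 1 to 4 were 0.0872, −0.0527, 0.0125 and 0.191, and 2 of the 8 samples correlated best with their own number. With the replicate block 25 genes were higher and 12 lower, and 17 lists were called.

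Of the 28 lists tested, 17 were called, 1 with an estimated correlation and 7 with fry's directional test, and at least 13 under every other alternative. Fry's mixed test, which ignores direction, called 19. With quantile normalization the lists of MHC class I presentation (adjusted p = 0.238), oxidative phosphorylation, nuclear (0.484), cholesterol and lipid metabolism (0.0827) and endothelial markers (0.0987) lost their call. Calls were also lost without the 3 libraries with under 15000 genes detected by the maturation, mitochondrial, cholesterol and endothelial lists, without the 3 keratinocyte-rich libraries by the MHC class I, interferon, oxidative phosphorylation, immediate-early and keratinocyte lists, with either covariate by the oxidative phosphorylation and mitochondrial lists, and with genes detected as a covariate by the keratinocyte list, for which the other covariate is no test since it is made of the same genes. The filter at a mean of 100 also ended the calls of the MHC class I, maturation and oxidative phosphorylation lists. Camera sets a list against all other tested genes. The median of all tested genes was −0.49, and −0.07 among those with a mean log2 value above 8. An upward call of a list with a small median is relative to that level. Of the lists called, 13 kept their call whichever single library was left out. On simulated data 18% of 4-fold changes were called, so that changes of that size are mostly not detectable with this spread.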

Other observations

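All gene lists and tests in this part were chosen after the values were seen, except that the prediction for the time of day was written before its result. The list-test p-values are adjusted over the 5 added lists. Since these lists were chosen from the same values, their p-values can be small by that choice alone. They only describe the lists, are no support for a change, and cannot be set beside those of the fixed lists.

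Activating and paired myeloid receptors were higher as a set (28 tested, 7 rose and none fell over all genes, 20 higher adjusted over the list alone, median 5.49, camera adjusted p = 3.76e-24, 0.00975 with an estimated correlation), among them Lilr4b, by 5.32, and Pilra, by 8.70. Chemoattractant receptors (21 tested, 3 rose, 13 higher and 1 lower adjusted over the list alone, median 4.31, 4.09e-12, 0.0139 with an estimated correlation) included Ccr1, by 4.45. The Ms4a family (8 tested, 4 rose, all 8 higher adjusted over the list alone, median 4.60, 7.44e-12, 0.00975 with an estimated correlation) included Ms4a6d, by 3.64. Matrix metalloproteinases and inhibitors (10 tested, 3 rose and 1 fell, 7 higher and 1 lower adjusted over the list alone, median 4.07, 1.81e-06, 0.0139 with an estimated correlation) included Mmp12, by 4.07, and Mmp13, by 8.97. Members of the receptor and Ms4a families resemble each other, and the assignment of reads among them is uncertain. As with the neutrophil and monocyte lists, the mean of the receptor list was lowest among the IMQ libraries in IMQ replicate 4, at 9.29. Whether these rises come from other myeloid cells was not tested.

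Clock genes were lower as a set (15 tested, 2 fell and none rose over all genes, 1 higher and 4 lower adjusted over the list alone, median −2.76, −2.13 with genes at 0 in a group set to their bound, camera adjusted p = 0.000488, 0.103 with an estimated correlation). Per2 and Hlf fell, each with no read in any IMQ library. Their median lay at percentile 0.03 of 10000 random lists matched on mean level, a description given with no prediction. Tissue taken at another time of day may be a cause: 4 genes of the opposite phase would then be higher, and had a median of −0.996 (SD 1.27) against −3.81 for the others. That value met the bound written beforehand against this explanation, 0 or below, but not by more than its SD, a margin added after the result was seen, so the explanation stays open.

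Il6 had 1336 reads and Mcpt8 1237 in IMQ replicate 2, against at most 45 and 4 in any other library.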
